A study of Mus musculus with 4 samples.

How the data were processed

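RNA was measured by mRNA sequencing in 4 libraries of mouse primary hepatocytes, 2 from wild-type (WT) mice and 2 from mice lacking Prom1 (KO). Per the labels, the animals were age-matched C57BL/6 males of 8 weeks and the replicates of a group were biological. Freshly isolated liver cells were allowed to attach in a serum- and dexamethasone-containing medium and were then kept without serum overnight before lysis in TRIzol. Libraries were made with a stranded Illumina TruSeq mRNA kit, per the labels' protocols. The submitters' processing notes name STAR 2.5.0, Cufflinks, Cuffdiff 2.2.1 and the mouse build mm10, with no role or order. The annotation used for counting and its strand setting are not given in the sources used here.

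The authors deposited a gene table with 1 value per library, whose unit was read as FPKM (fragments per kilobase of transcript, scaled to a fixed number of mapped fragments). That reading rests on the tools in the processing notes and on the values, which are not whole numbers and have library totals between 498348 and 546967, because no column name states the unit. FPKM values are already divided by transcript length and library depth, so no count model was applied. Whole fragments could not be recovered, because Cufflinks shares fragments among transcripts. From the lowest steps of the values in 3532 genes with 1 annotated transcript, and an assumed fragment length of 200 bases, the libraries were estimated to hold 17900000 (WT 1), 16300000 (WT 2), 16200000 (KO 1) and 15200000 (KO 2) fragments. At that depth a transcript of 2 kb at 1 FPKM rests on 30.4 to 35.9 fragments. Cufflinks can also list a gene at 0 when its estimate fails: Alb was listed at 0 in WT 2 against 27103, 25551 and 32670 FPKM in WT 1, KO 1 and KO 2. A value of 0 is therefore described below as listed at 0.

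Of 22079 gene identifiers in the table, 21984 were matched by identifier to a symbol and position in GENCODE M21, which annotates the same build. The 4 columns were matched to samples by their titles, and no other per-sample column was present. Values were transformed as log2(FPKM + 1), so that differences between libraries are on that scale and understate the change of genes with low values. Genes with a mean of at least 1 FPKM over the 4 libraries were tested (10407 genes). The KO libraries were compared with the WT libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with genotype as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Prom1 itself lay under the expression filter and was read from the same model fitted to all genes with a value above 0 in at least 1 library (15152 genes). An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so no such test could pass, and the limma p-values borrow their spread from all genes.

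Before the data were examined, 53 gene lists were fixed for hepatocyte functions, culture stress, signalling pathways, other liver cell types and the chromosomal neighbours of Prom1. The 46 lists with at least 5 tested members were compared with all other genes by camera (limma) with its preset inter-gene correlation of 0.01, adjusted over the 46 lists. Camera with a correlation estimated from the data, which leaves it the 2 residual degrees of freedom of the libraries, was run as an alternative. Fry was run as well; it tests whether a list's genes move at all, in 1 direction or in either, and does not compare the list with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Library levels of a list are medians over its members of log2(FPKM + 1) relative to the gene's mean over the 4 libraries. Lists of marker genes describe levels in bulk libraries and assign no cell types.

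The genes named in the text follow a rule also fixed before the data were examined. It takes Prom1 first. It then takes, because fewer than 20 genes passed the threshold, the 12 genes with the highest and the 12 with the lowest moderated t, leaving out predicted or unnamed gene models. For each list called by camera or described, it takes up to 4 members with the largest absolute log2 change. Further members of the hypoxia, glycolysis and macrophage lists and genes called with a library left out are named outside this rule, after their values were seen, and a few genes the rule takes are not reported here.

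The comparison was tested on simulated data in which 200 of 10407 genes were changed, 2 libraries against 2, 20 times. Means were those of the real genes, and spreads were those that limma had moderated toward the trend. It recovered 26.9% of genes changed by 0.5 on the log2 scale, 90.4% of those changed by 1 and 99.9% of those changed by 2, and 9.54% of its calls were false, above the nominal share. Moderated spreads are more alike than the genes' own, so these shares can overstate recovery in the real data. There, Pck1 with a log2 difference of -1.18 did not pass (limma adjusted p = 0.239). Camera was tested on simulated lists of 20 genes. With the preset correlation it called 3% of unchanged lists at an unadjusted p under 0.05 when genes varied independently, and 33.9% when they shared the median correlation estimated for the real lists, 0.19. With an estimated correlation, lists shifted by 0.4 on the log2 scale were called after adjustment in 99.1% of cases with independent genes and in 4.88% with that shared correlation.

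Alternatives covered the pseudocount, the filter, 3 ways of scaling the libraries, 2 settings of the spread model, the replicate number as a block, each library left out in turn, and, chosen after seeing the data, the removal of Alb. Counts tools were not used because no counts were analysed here, and Cuffdiff's own test results were not used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the plots.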

Results

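The libraries came from primary hepatocytes, the main parenchymal cells of the liver, isolated from WT and Prom1-deficient mice and kept overnight without serum (n = 2 biological replicates per genotype). The comparison asks how loss of Prom1 changes the hepatocyte transcriptome under serum-free conditions. Between 10327 and 10424 genes reached 1 FPKM in a library, and the estimated depth was 15200000 to 17900000 fragments.

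Prom1 encodes a membrane glycoprotein that binds cholesterol and sits in plasma-membrane protrusions. The gene (ENSMUSG00000029086) lies on the minus strand of chromosome 5, 43993620 to 44102032 in mm10. Prom1 stood at 0.571 FPKM in WT 1 and 1.22 FPKM in WT 2, was listed at 0 in KO 1 and stood at 0.0458 FPKM in KO 2. Its log2(FPKM + 1) was lower in the KO libraries, with a difference of -0.87 (SE 0.19). The limma p was 0.00935 unadjusted, and the adjusted p was 0.755 over the 15152 genes fitted; the exact permutation test cannot go below 0.333 here. The unadjusted limma p was 0.0982 without KO 1 and 0.0856 without KO 2, while the direction was the same. The 12 tested neighbours of Prom1 on its chromosome had a median log2 difference of -0.03 (camera adjusted p = 0.799).

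Pck1 and Pfkl, genes of glucose metabolism, had the lowest moderated t of the named genes. Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, stood at 16.3 ± 0.859 FPKM in WT and 6.66 ± 0.399 FPKM in KO (SD, n = 2), a log2 difference of -1.18 (SE 0.12). Pfkl, the liver-type phosphofructokinase, stood at 18.7 ± 0.551 and 8.05 ± 0.889 FPKM, a log2 difference of -1.12 (SE 0.12). Bnip3, a mitochondrial protein induced in hypoxia, stood at 95.3 ± 28.6 and 30.6 ± 2.11 FPKM, a log2 difference of -1.58 (SE 0.20). The oxygen-dependent prolyl hydroxylase gene Egln3 (-1.13) and the hypoxia-induced gene Ndufa4l2 (-1.57) were also among the 12, with Depp1 (-1.68), the scavenging chemokine receptor gene Ackr3 (-1.31), the thymosin gene Tmsb10 (-1.03), Selenbp1 (-1.56), Zfp970 (-0.73), the sialyltransferase gene St3gal1 (-0.89) and the acute phase gene Orm2 (-0.95). At the other end, the cytokine subunit gene Il23a stood at 1.55 FPKM on average in WT (1.72 and 1.37) and at 7.04 and 6.25 FPKM in KO, a log2 difference of 1.59 (SE 0.16). Dio3, which inactivates thyroid hormone, stood at 9.45 ± 1.44 and 23.4 ± 1.09 FPKM, a log2 difference of 1.23 (SE 0.13). Fads2, a desaturase of polyunsaturated fatty acid synthesis, stood at 47.3 ± 8.35 and 94.6 ± 3.21 FPKM, a log2 difference of 0.996 (SE 0.14). The remaining 9 of the 12 highest were Lhfpl2 (1.06), Prnd (1.17), the macrophage receptor gene Marco (0.87), Taf12 (0.75), the liver pyruvate kinase gene Pklr (0.63), Isy1 (0.63), Cops8 (0.61), the urokinase receptor gene Plaur (0.60) and the stress-induced phosphatase subunit gene Ppp1r15a (0.52).

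None of these genes passed the test across all genes. By limma, 0 of 10407 genes had an adjusted p under 0.05, and the lowest adjusted p was 0.239. At an unadjusted p under 0.05, 759 genes differed, 323 higher and 436 lower in KO, where chance gives about 520. That count was 318 without WT 2, 787 without WT 1, 814 without KO 1 and 1227 without KO 2, so without WT 2 it lay below the number chance gives. Both KO libraries lay above or below both WT libraries for 38.1% of genes, where chance gives 33.3%. Correlations between libraries of different genotype ran from 0.976 to 0.988, against 0.9858 for WT 1 with WT 2 and 0.9857 for KO 1 with KO 2. The highest of them thus exceeded both correlations within a genotype. WT 1 and KO 1 each decided whether any gene was called: 8 genes had an adjusted p under 0.05 by limma without WT 1 and 5 without KO 1, against 0 without WT 2 and 0 without KO 2. These genes were chosen after their values were seen. The 8 without WT 1 were Depp1, Selenbp1, Bnip3, Cyp2b10, Tpm2, Gm13889, Alb and Mid1, and the 5 without KO 1 included Pkm, Cldn4, Slc39a2 and Gm42791. Mid1 stood at 50.2 FPKM in WT 2 against 0.747 in WT 1, 0.579 in KO 1 and 0.211 in KO 2. Several named genes overlap another gene on the genome or have a close copy, and their values are uncertain to that extent. Prnd and Isy1 overlap a gene on the same strand, Ndufa4l2, Depp1, Pklr and Ppp1r15a overlap a gene on the opposite strand, and Selenbp1 and Orm2 have near-identical family members.

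**Figure D1:**
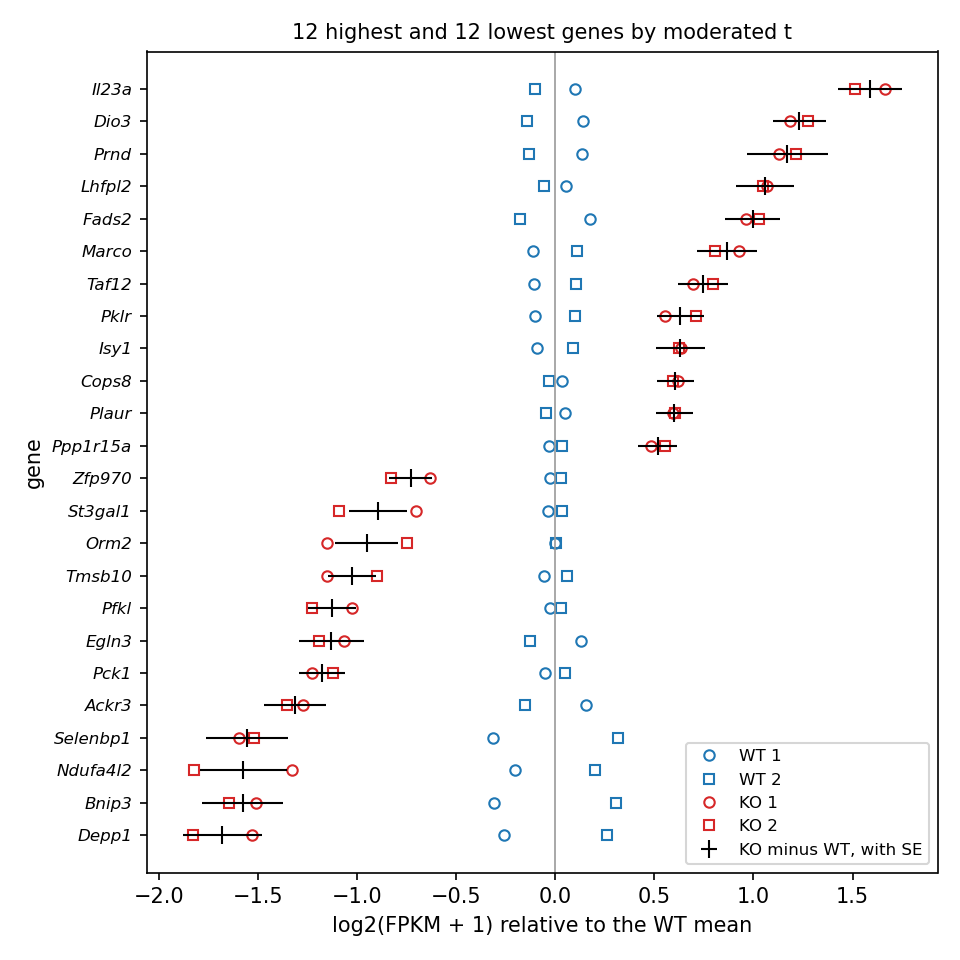
The 12 genes with the highest and the 12 with the lowest moderated t, KO against WT. The horizontal axis is log2(FPKM + 1) relative to the WT mean, open symbols are the 4 libraries, and black marks are the limma difference with its SE. For each of the 24 genes both KO libraries lie on the same side of both WT libraries, from -1.68 for Depp1 to 1.59 for Il23a, and none passed the adjusted threshold.

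Genes induced by hypoxia were lower as a group in the KO libraries. Of 17 members tested, 15 had a lower and 2 a higher value in KO, and the median log2 difference was -0.40. Both KO libraries lay below both WT libraries for 12 members, while 38.1% of all genes tested had libraries apart in either direction. Members of a list can vary together, so that share does not say how unusual such a count is. Bnip3 and Egln3 led this list, followed by Ankrd37, at 2.08 ± 0.00319 FPKM in WT and 0.432 ± 0.233 in KO (SD, n = 2; log2 difference -1.12), and the stress-response gene Ndrg1, at 34.2 and 53.9 FPKM in WT and 21.6 and 20.6 FPKM in KO (-0.99). Named outside the rule, the 2 members that were not lower were the glucose transporter gene Slc2a1 (0.31) and the adrenomedullin gene Adm (0.00), whose sign changed with the pseudocount, with rescaling to a common total and with the library left out. Camera called the list (adjusted p = 7.52e-09), with an adjusted p = 0.747 with an estimated correlation. No member passed over all genes tested, and 9 members, all lower, passed when adjusted over the list alone.

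Glycolytic genes separated the genotypes at every member tested. All 17 members had non-overlapping libraries, against 38.1% of all genes tested, with 14 lower and 3 higher in KO and a median log2 difference of -0.47. The muscle-type pyruvate kinase gene Pkm stood at 24.8 ± 2.23 FPKM in WT and 10.3 ± 4.36 in KO (SD, n = 2; log2 difference -1.24). The glucose-6-phosphate isomerase gene Gpi1 stood at 151 ± 1.42 and 97.3 ± 16.5 FPKM (-0.64). The 3 higher members were Pklr (0.63) and, named outside the rule, the glucose transporter genes Slc2a2 (0.43) and Slc2a1 (0.31), whose products act at the last step and at glucose entry. Camera called the list lower (adjusted p = 3.50e-07; adjusted p = 0.747 with an estimated correlation). Fry gave an adjusted p of 0.293 for movement in 1 direction and 0.00734 for movement in either direction. By limma, 0 members passed over all genes tested and 15 passed when adjusted over the list alone, 12 lower and 3 higher. Pgk1, Ldha and Slc2a1 are members of both this list and the hypoxia list.

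**Figure D2:**
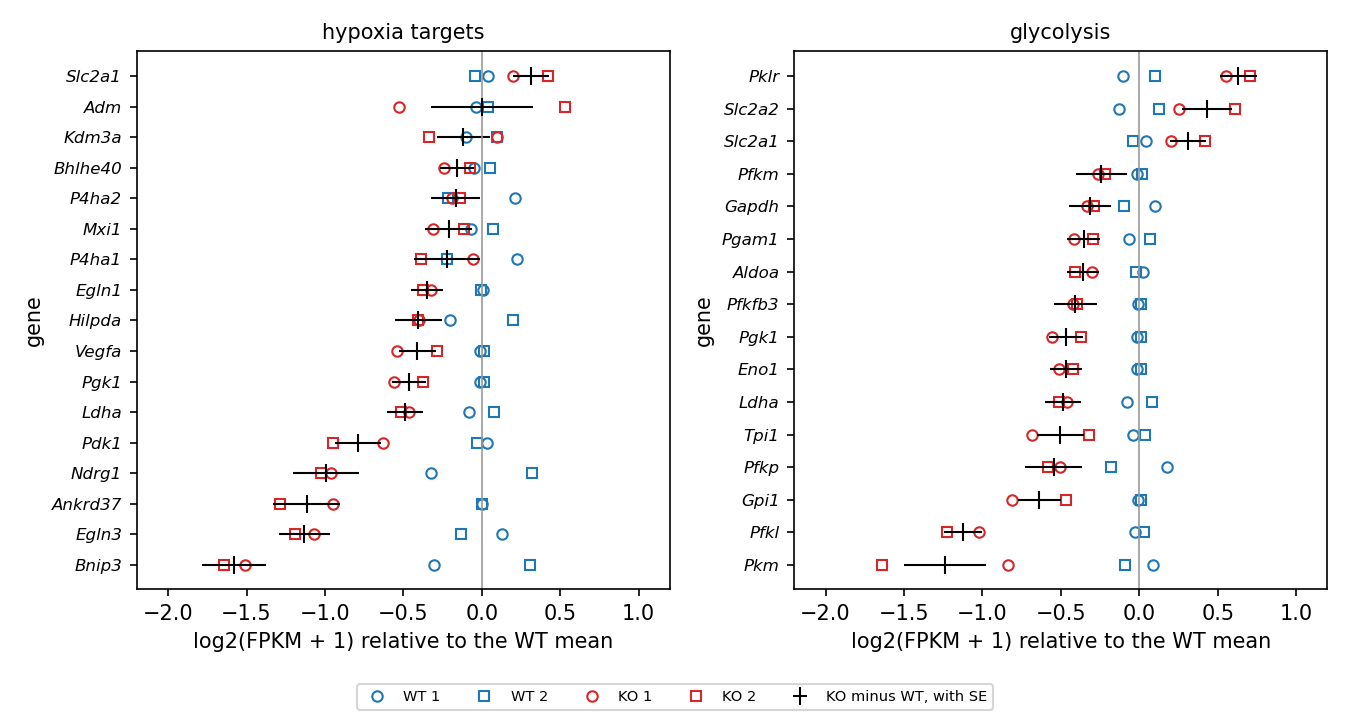
Members of the hypoxia list (left) and the glycolysis list (right), with log2(FPKM + 1) relative to the WT mean on the horizontal axis. Open symbols are the 4 libraries and black marks the limma difference with its SE. In the glycolysis panel, which shows 16 of the 17 members, 13 genes lie lower in both KO libraries than in both WT libraries and 3 lie higher, and in the hypoxia panel 12 lie lower and 1 higher.

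Genes that hepatocytes use in fasting were also lower as groups. The list of gluconeogenic and glucagon-cAMP targets had 11 of 15 members lower in KO, with a median log2 difference of -0.24. Besides Pck1 it held the glucose-6-phosphatase gene G6pc (2.77 ± 0.812 and 0.879 ± 0.384 FPKM, log2 difference -1.004), the glucose-6-phosphate transporter gene Slc37a4 (39.2 ± 12.3 and 21.2 ± 2.24 FPKM, -0.83) and Pdk4 (7.32 ± 2.84 and 3.69 ± 0.129 FPKM, -0.79; all SD, n = 2). Without WT 2, Slc37a4 differed by -0.51 and Pdk4 by -0.43. Camera called it (adjusted p = 8.15e-05; adjusted p = 0.747 with an estimated correlation), and 3 members passed when adjusted over the list alone. Targets of the glucocorticoid receptor, which dexamethasone, a part of the attachment medium, can activate, were lower for 14 of 16 members, with a median of -0.32. Among them the co-chaperone gene Fkbp5 stood at 18.7 ± 2.83 and 9.96 ± 1.57 FPKM (-0.85), Zbtb16 differed by -0.60 and Lcn2 (5709 ± 246 and 3731 ± 1258 FPKM) by -0.65, which was -0.30 without KO 2 and -1.005 without KO 1. Camera called that list as well (adjusted p = 1.45e-06; adjusted p = 0.747 with an estimated correlation), and 3 members, Pck1, Fkbp5 and Zbtb16, passed when adjusted over the list alone. Genes of fatty acid oxidation and ketogenesis were lower for 19 of 25 members, with a median of -0.16, including the regulator gene Ppara (24.7 ± 4.67 and 15.8 ± 0.821 FPKM, -0.60). Cd36 (7.27 ± 0.0674 and 4.45 ± 2.57 FPKM) differed by -0.69, by -0.19 without KO 2 and by -1.19 without KO 1. Cyp4a14 stood apart at 1.44 with overlapping libraries (2.85 ± 2.24 and 11.4 ± 11.3 FPKM), and 0 members passed over the list alone. Camera gave an adjusted p of 0.000694 for this list (adjusted p = 0.747 with an estimated correlation).

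Periportal hepatocyte markers, which mark the zone of the liver lobule nearest the portal vein, were lower for 12 of 13 members with a median of -0.35. The arginase gene Arg1 stood at 130 ± 51.6 FPKM in WT and 55.4 ± 25.6 in KO (SD, n = 2; -1.24), Sds differed by -1.12 and Hal by -1.05. Arg1 differed by -0.76 without KO 1 and Hal by -0.69 without WT 2. Camera called the list (adjusted p = 1.79e-05, and 0.747 with an estimated correlation), and Pck1 and Sds, 2 members, passed when adjusted over the list alone. Pck1 is also a member of the gluconeogenic and glucocorticoid lists, so these lists are not independent results. Its library levels did not separate the genotypes: the median was 0.04 in WT 1, 0.40 in WT 2, -0.40 in KO 1 and 0.07 in KO 2. KO 1 was also the library with the highest medians of sinusoidal endothelial (0.41) and stellate cell (0.68) markers, the latter with 6 tested members. KO 2 had the lowest medians of both (-0.36 and -0.23), yet WT 2 and not KO 2 was highest in periportal markers. Whether other cell types account for the levels of this list, or of the lists below that were most extreme in KO 1, was not tested. The median log2 difference was -0.18 without KO 1, -0.185 without WT 2, -0.58 without WT 1 and -0.70 without KO 2. Arg1, Sds and Hal also belong to the urea cycle and amino acid catabolism list, which was not called (median -0.14, camera adjusted p = 0.0876). Pericentral markers had a median of 0.15 (camera adjusted p = 0.162), with Glul at -0.39. Cyp1a2 (65.3 ± 0.208 and 97.3 ± 41.9 FPKM) differed by 0.50, by 0.05 without KO 2 and by 0.95 without KO 1. Bile acid synthesis and transport genes were lower for 16 of 20 members (median -0.24), including Cyp8b1 (4.43 ± 0.174 and 2.21 ± 1.32 FPKM, -0.82) and Abcg5 (-0.55), while the export pump gene Abcc4 stood at 0.61. Without KO 1 the value of Cyp8b1 was -0.39 and that of Abcc4 0.24, and without WT 2 that of Abcg5 was -0.34. This list, too, was lowest in KO 1 (median -0.28), the library highest in endothelial and stellate cell markers. Camera called this list with all libraries (adjusted p = 0.00911; adjusted p = 0.776 with an estimated correlation) but gave an adjusted p of 0.658 without KO 1 (median -0.03), 0.142 without WT 2 (median -0.12) and 0.0691 with a filter at a mean of 5 FPKM. The median was -0.38 without KO 2, and 0 members passed over the list alone.

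Acute phase genes and targets of interleukin-6 were lower for 28 of 30 members, with a median log2 difference of -0.40. Orm2 stood at 544 ± 1.45 FPKM in WT and 284 ± 55.9 in KO (SD, n = 2), and the serum amyloid gene Saa3 at 321 ± 137 and 104 ± 37.8 FPKM (-1.60). Saa2 (2995 ± 166 and 1947 ± 914 FPKM) differed by -0.70, by -0.21 without KO 2 and by -1.20 without KO 1, and Serpina3n (1490 ± 535 and 896 ± 93.6 FPKM) differed by -0.69, by -0.31 without WT 2 and by -1.06 without WT 1. Camera called the list (adjusted p = 9.39e-08; adjusted p = 0.747 with an estimated correlation), and Orm2 alone, 1 member, passed when adjusted over the list alone. Interferon-stimulated genes were lower for 26 of 30 members, with a median of -0.24, among them Mx2 (-0.70), Rsad2 (-0.70), Ifit3 (-0.65) and Isg15 (-0.54). Isg15 differed by -0.20 without KO 1 and Ifit3 by -0.38 without WT 2. Camera gave an adjusted p of 3.08e-06 (adjusted p = 0.776 with an estimated correlation), and 0 members passed over the list alone. In both lists the highest library median was in WT 2 and the lowest in KO 1, where endothelial and stellate cell markers were highest. The median log2 difference of acute phase genes was -0.26 without KO 1, and that of interferon-stimulated genes was -0.075 without KO 1 (camera adjusted p = 0.0398) and -0.43 without KO 2.

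Cholesterol synthesis genes were higher as a group in KO. Of 24 members 22 had a higher value, with a median log2 difference of 0.30. Both KO libraries lay above both WT libraries for 12 and below them for 0, while 38.1% of all genes tested had libraries apart in either direction. The farnesyl diphosphate synthase gene Fdps stood at 83.2 ± 26.5 FPKM in WT and 157 ± 27.3 in KO (SD, n = 2; 0.94), Cyp51 at 24.0 ± 3.67 and 36.8 ± 9.56 FPKM (0.59), and Nsdhl differed by 0.58. Without KO 1 the value of Cyp51 was 0.32 and that of Nsdhl 0.28, and without WT 2 that of Fdps was 0.61. Camera called the list (adjusted p = 9.63e-07; adjusted p = 0.747 with an estimated correlation), and 0 members passed over the list alone. The library medians ran from -0.25 in WT 2 to 0.27 in KO 1, which was also highest in endothelial and stellate cell markers. The median log2 difference was 0.11 without KO 1 (camera adjusted p = 0.0316) and 0.17 without WT 2. The fatty acid and triglyceride synthesis list was not called (median 0.05, camera adjusted p = 0.201), although its desaturases Fads2 (0.996), Fads1 (0.71) and Scd1 (0.66) had the 3 largest values. Without WT 2 that of Fads1 was 0.47 and that of Scd1 0.19, and Scd1 reached 1.12 without WT 1. Fads2 was the 1 member that passed when adjusted over the list alone.

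Targets of ATF4 and of the amino acid response were higher for 13 of 17 members, with a median of 0.26. The serine synthesis genes Phgdh (10.4 ± 2.86 FPKM in WT and 19.4 ± 5.52 in KO, 0.84) and Psat1 (40.8 ± 2.28 and 61.6 ± 12.4 FPKM, 0.57, SD, n = 2) and the mitochondrial folate gene Aldh1l2 (0.66) were higher. Shmt2, the mitochondrial serine hydroxymethyltransferase, was lower (77.8 ± 4.11 and 55.7 ± 2.24 FPKM, -0.47). Shmt2 overlaps Ndufa4l2 (-1.57) on the opposite strand, and the strand setting used for counting is not given, so its value is uncertain to that extent. Camera called the list (adjusted p = 0.000432; adjusted p = 0.747 with an estimated correlation), and 0 members passed over the list alone. The median of the ATF4 list was 0.41 without KO 1 and 0.13 without KO 2, and the value of Psat1 was 0.37 without KO 1. Unfolded protein response genes were not called (median 0.05, camera adjusted p = 0.162), and Ppp1r15a was the 1 member that passed when adjusted over the list alone. Circadian clock genes were lower for 12 of 14 members (median -0.21), including Tef (-0.45, and -0.20 without KO 1) and Cry2 (-0.45). The clock list was lowest in KO 1 (median -0.17), the library highest in endothelial and stellate cell markers. Camera gave an adjusted p of 0.00705 for the clock list (adjusted p = 0.747 with an estimated correlation), which was 0.181 without KO 1 (median -0.09), and 0 members passed over the list alone. The clock median was -0.34 without WT 1 and -0.13 without WT 2. Mesenchymal and dedifferentiation genes were higher for 16 of 22 members (median 0.15), among them Cd44 (0.79, and 0.52 without WT 2) and Anxa3 (0.66, and 0.31 without KO 1). Tmsb10 went the other way and was the 1 member that passed over the list alone, and Fn1 stood at -0.78 with overlapping libraries (-0.30 without WT 2). Camera gave an adjusted p of 0.0436 (adjusted p = 0.747 with an estimated correlation), which was 0.260 without WT 2 and 0.167 without KO 1. It was 0.241 without the expression filter and 0.105 with a filter at a mean of 5 FPKM.

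Across the 46 lists, camera called 13, 10 lower and 3 higher in KO, and 0 with an estimated correlation, where the lowest adjusted p was 0.747. In the simulations that setting called only 4.88% of lists shifted by 0.4 at the shared correlation of 0.19. Its 0 calls therefore do not show that the lists were unshifted. Fry called 0 lists for movement in 1 direction, with a lowest adjusted p of 0.0734 for the hypoxia list. Of the marker lists of other liver cell types, the 3 with at least 5 tested members were not called between genotypes, and those of cholangiocytes and progenitors (3 tested members), erythroid cells (1), lymphocytes (0), neutrophils (0) and mesothelial cells (0) were not tested. Sinusoidal endothelial markers had a median log2 difference of 0.06 (camera adjusted p = 0.748) and stellate cell and fibroblast markers 0.26 (camera adjusted p = 0.0958), and in both lists KO 1 was highest (0.41 and 0.68) and KO 2 lowest (-0.36 and -0.23). Kupffer cell and macrophage markers had a median of 0.02 (camera adjusted p = 0.0876). Hepatocyte identity genes had a median of -0.12 but a mean of 0.29, since Alb, listed at 0 in WT 2, had a log2 difference of 7.46 (camera adjusted p = 0.118, direction lower). The transcription factor gene Hnf4a stood at 93.1 ± 3.83 FPKM in WT and 62.2 ± 3.84 in KO (SD, n = 2; -0.58) and was the 1 member of that list that passed when adjusted over the list alone.

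**Figure D3:**
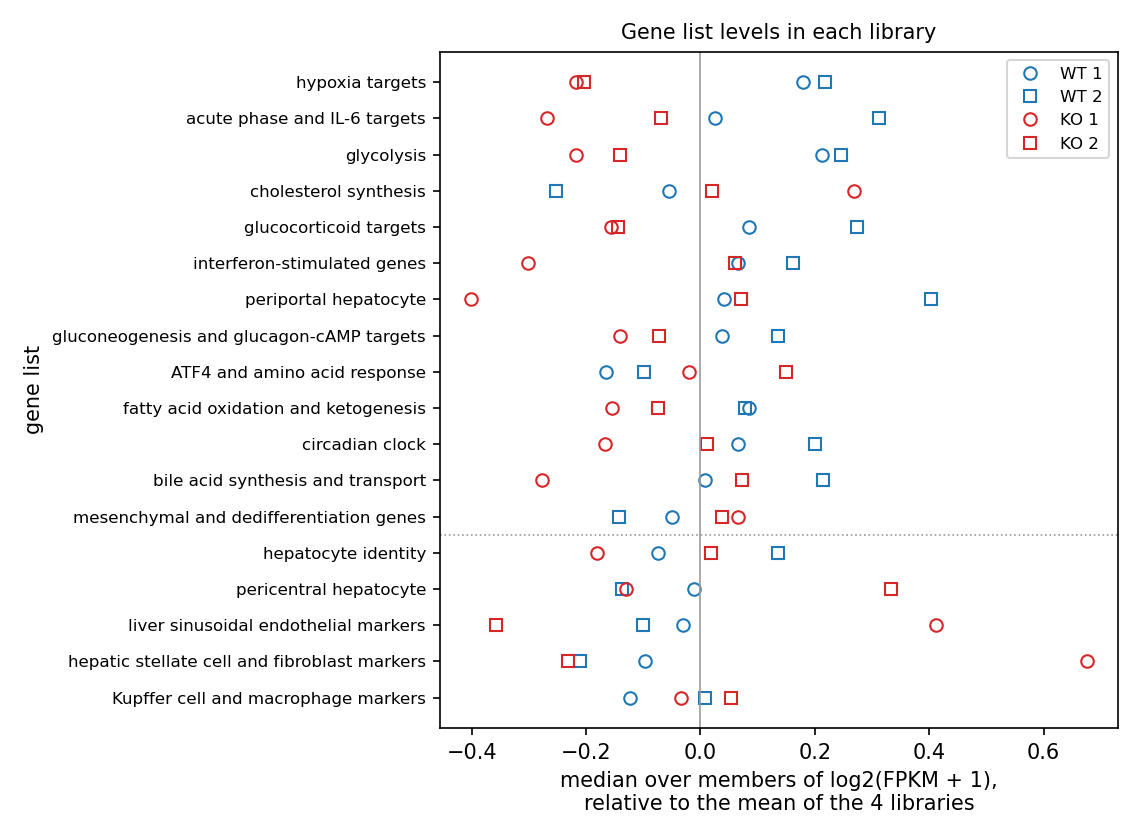
Levels of the 13 called gene lists (above the dotted line) and 5 cell type lists (below it) in each library, as the median over members of log2(FPKM + 1) relative to the mean of the 4 libraries. Blue symbols are WT and red symbols KO. For hypoxia targets the WT libraries lie at 0.18 and 0.22 and the KO libraries at -0.22 and -0.20, while for periportal markers KO 2 (0.07) lies above WT 1 (0.04).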

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

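The removal of Alb, and for lists the pseudocount of 0.5, the missing filter and the scalings by total and by median of ratios, were chosen after seeing the data. The count of 0 genes past the threshold by limma, with 759 at an unadjusted p under 0.05, was also 0 under 13 of 15 alternatives, and ran from 0 to 8 with a library left out, where the group with 1 library left is assumed to vary like the other. For several of the genes called without WT 1 or without KO 1, the library left alone in its group stood apart from all others. In WT 2, Alb was listed at 0 and Mid1 stood at 50.2 FPKM. In KO 2, Slc39a2 stood at 0.234 FPKM against 7.80 to 10.4 FPKM elsewhere, and Gm42791 at 14.1 FPKM against values near 0. Others, such as Depp1, Bnip3 and Pkm, had both KO libraries below both WT libraries. The cause was not tested further. In the simulations, camera with an estimated correlation called lists shifted by 0.4 in 99.1% of cases with independent genes. At the shared correlation of 0.19 it called 4.88% of them. A result of 0 lists with that setting therefore cannot tell absent shifts from missed ones. Fry, which does not compare a list with other genes, called 0 lists for movement in 1 direction and 1, glycolysis, for movement in either. The cause of that lower count was not tested. Camera called 13 lists with its preset correlation and 0 with an estimated one. The count was 15 to 22 with a library left out (21 without KO 1, 22 without KO 2), and 10 of the 13 were called in each of the 4 fits, the exceptions being circadian clock, bile acid and mesenchymal genes. The other settings gave 12 to 15 lists, and bile acid genes were lost with the filter of 5 FPKM and mesenchymal genes with it and with no filter. The replicate numbers are not known to pair the libraries (correlation of deviations 0.15 over 2 pairs); with the replicate number as a block, 0 genes and 17 lists were called, all 13 among them, and no named gene was called. The log2 difference of Prom1 lay between -1.12 and -0.62 with a library left out and had an unadjusted limma p over 0.05 without KO 1 and without KO 2; with a mean under 1 FPKM it has no value under the filter of 5 FPKM. It was -2.96 with a pseudocount of 0.1. Directions of named genes were the same except for Adm (-0.0073 with a pseudocount of 0.1, -0.0031 with 0.5, -0.0039 rescaled to a common total, and -0.53 to 0.53 with a library left out) and, with a library left out, P4ha1 (-0.44 to 0.0034), P4ha2 (-0.38 to 0.048), Kdm3a (-0.33 to 0.10), Ccn2 (-0.056 to 0.81), Dcn (-0.22 to 0.99) and Hpd (-0.79 to 0.12). Cuffdiff's own q-values and count tools, listed as alternatives, were not run, as neither fits the values used here. Depth limits genes near 1 FPKM, which rest on about 30.4 to 35.9 fragments at 2 kb.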

Other observations

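The leave-one-out and scaling values of the hypoxia list were chosen as tests after the results were seen, as were the other splits of the libraries, the simulated p-values of single lists, and the test of macrophage markers. Several genes of the cell surface, the cytoskeleton and pericellular proteolysis had non-overlapping libraries and stood outside the called lists. Plaur, the receptor of urokinase, stood at 44.5 ± 2.11 FPKM in WT and 68.0 ± 0.352 in KO (SD, n = 2; log2 difference 0.60). Timp1 stood at 0.522 ± 0.286 and 2.53 ± 0.642 FPKM (1.21), Tagln at 1.65 ± 0.313 and 4.17 ± 0.899 FPKM (0.96), and the YAP target Ankrd1 at 4.08 ± 0.323 and 7.07 ± 0.218 FPKM (0.67). Timp1 and Tagln are also members of the stellate cell and fibroblast list, which was not called (median 0.26, camera adjusted p = 0.0958). In that list 2 of 6 tested members, both higher, passed when adjusted over the list alone. Which cells expressed these genes was not tested. The list of TGF-beta targets had a median of 0.06 and a mean of -0.04 (camera adjusted p = 0.799, direction higher), and the YAP-TEAD list had a median of 0.22 (camera adjusted p = 0.0597; adjusted p = 0.747 with an estimated correlation).

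Prominin-1 is a protein of membrane protrusions, and genes of such structures were looked at as fixed lists. In the list of cilia, microvilli and cholesterol-rich membrane, the villin gene Vil1 stood at 2.62 ± 0.389 FPKM in WT and 4.82 ± 1.09 in KO (SD, n = 2; 0.68), the caveolin gene Cav2 at 7.77 ± 1.14 and 12.9 ± 1.36 FPKM (0.66) and the ezrin gene Ezr at 3.09 ± 0.140 and 4.61 ± 0.878 FPKM (0.45), while Pdzk1 differed by -0.33. Without KO 1, Ezr differed by 0.29 and Pdzk1 by -0.12. Of 10 members 6 were higher and 4 lower, and the list was not called (median 0.09, camera adjusted p = 0.115), and Cav2 was the 1 member that passed when adjusted over the list alone. Among ERM proteins and protein kinase A subunits, the moesin gene Msn differed by 0.68 (0.39 without KO 1) and Slc9a3r1 by -0.35, both KO libraries lay above both WT libraries for 5 of 16 members and below them for 5, the list median was 0.04 and camera gave an adjusted p of 0.547. The autophagy genes Gabarapl1 (-0.46), Map1lc3b (-0.43) and Ulk1 (-0.37) had both KO libraries below both WT libraries, but of 19 members 8 were higher and 11 lower, both KO libraries lay above both WT libraries for 4 and below them for 6, and the list was not called (median -0.03, camera adjusted p = 0.162).

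The lower level of hypoxia and glycolysis genes in KO may reflect loss of Prom1 or a difference between the cultures. A deviating library is argued against by the leave-one-out fits, whose highest camera adjusted p for the hypoxia list was 6.57e-07, with the direction lower in each. Under the 3 other scalings the hypoxia list's median log2 difference lay between -0.408 and -0.396. The median over all genes lay between -0.0041 and 0.0058 under them, so they could not have removed a shift of that size. What this shows is that no library-wide shift of that size was present. Without Pgk1, Ldha and Slc2a1, camera still called the glycolysis list lower (adjusted p = 6.63e-07, and 0.747 with an estimated correlation). The shared members alone therefore did not carry that call, but this does not make the glycolysis and hypoxia lists independent results. In 400 simulations, unchanged lists of the same sizes sharing the median correlation of 0.19 gave a camera p as low as observed in 0% of cases for hypoxia and 0.25% for glycolysis, and in 0% for both at their own estimated correlations (taken as 0 where negative). Those correlations were estimated within genotypes, with 2 residual degrees of freedom. They cannot register a difference between cultures that runs along with genotype, so the simulated shares do not exclude one. Other splits of the libraries gave lower camera p-values for other lists, as given below. Oxygen supply, cell density and plating day stay open, because the labels give no value for them, and an effect of the genotype was not tested apart from them.

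The lists called between genotypes are more doubtful as a whole. The genotype split called 13 lists, and the highest of the other splits called 14, so 2 of the 3 ways of pairing the 4 libraries gave as many, and 3 splits are too few for a share under 0.05. That other split sets replicate 1 against replicate 2, and it also called 5 of the 13: acute phase, cholesterol synthesis, interferon-stimulated, periportal and bile acid genes, whose library levels were most extreme in WT 2 and KO 1. The third split, WT 1 and KO 2 against WT 2 and KO 1, called 9 lists. At an unadjusted limma p under 0.05, the genotype split gave 759 genes, the replicate split 554 and the third split 218. Camera's lowest adjusted p was 8.67e-15 in the replicate split (complement and coagulation) and 1.99e-14 in the third (major urinary proteins). Both lay below the lowest of the genotype split, 7.52e-09 for the hypoxia list. Correlation among a list's genes is a candidate explanation for some calls, since simulated unchanged lists with the median estimated correlation passed camera's preset test in 33.9% of cases at an unadjusted p under 0.05. The simulated share with a camera p as low as observed, at each list's own estimated correlation (taken as 0 where negative), ran from 0% to 20.2% over the 13 lists, and at the median correlation from 0% to 19%; it depended on the correlation assumed, being 19% and 2.5% for interferon-stimulated, 20.2% and 10.8% for bile acid, 8.5% and 0.25% for periportal, 8% and 6.75% for circadian clock, 0% and 6.5% for fatty acid oxidation, 0% and 2.25% for ATF4 and 0.5% and 19% for mesenchymal genes.

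Marco, Lyz2 and Cd5l, genes of Kupffer cells and other macrophages, were higher in both KO libraries (log2 differences 0.87, 0.85 and 0.70) and passed limma's threshold when adjusted over the list alone, though not over all genes tested. More Kupffer cells in the KO cultures could be the source, but those cells also bring complement C1q and other abundant transcripts. Marco, Lyz2 and Cd5l were picked because they passed, so it was fixed by that choice that the other markers lie below them. The other 10 markers had a median log2 difference of -0.012 (SD 0.22 over markers). Among C1qa, C1qb, C1qc, Csf1r, Tyrobp, Ctss and Clec4f, chosen after the values were seen, the highest value was 0.05. These values show no rise shared by the other markers and do not exclude more Kupffer cells. C1qa, named outside the rule like the other markers compared, stood at 3.62 and 3.78 FPKM in WT and 3.01 and 3.55 FPKM in KO, while Adgre1 (0.47, and 0.28 without KO 1) went with the trio. A change in the state of the macrophages present, or expression of these genes by the hepatocytes, stays open and was not tested.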
